A study of Mus musculus with 6 samples.

How the data were processed

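Poly(A)+ RNA of mouse liver was sequenced in 6 libraries, 3 labelled as injected with vehicle and 3 with an adenovirus that overexpresses Chrna4, per the labels. The labels give each library its own liver number and state no batch, day or pairing, so replicate numbers, which the deposited column names also carry, only name libraries here. TopHat2 and HTSeq, with the builds mm10 and GRCm38, are named in the submitters' processing notes without versions or roles; the annotation, the counting of strand and the treatment of reads that match several genes are not given in the sources used here.

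The deposited table holds, per the file headers, a gene symbol with an Ensembl gene number, a log2 fold change, a mean log2 abundance, a p-value and an adjusted p-value of the authors' own comparison, and a signal per library. Each deposited signal was a whole multiple of the value of 1 read in its column: after dividing by that value, 100% of values lay within 0.01 of a whole number. The signal is therefore reads per 1000000 reads of a scaled library total (CPM), and the factors of scaling that it implies equal those of the TMM method of edgeR recomputed from the recovered reads. Recovered reads numbered 14959300 to 22440300 per library over the 14492 genes in the table, and no gene had fewer than 10 reads over the 6 libraries; a filter applied by the authors is not stated. The authors' log2 fold changes and p-values were recomputed from the recovered reads with edgeR's exact test and tagwise dispersions, and the largest difference in log2 fold change was 1.33e-05. Both other sheets of the workbook, of which only the gene names were used, hold genes that the authors selected.

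The design, the gene lists, the rule for named genes and the settings to vary were fixed before the data were examined. The design named the quasi-likelihood test of edgeR as the main test for a count table, and limma for normalized values without counts. Because the table holds normalized values, the main test was limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trend) on log2(value + 1) of the 12099 genes with a mean of at least 1 over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The other 2393 genes were not tested. Fold changes are Chrna4-labelled over vehicle on the log2(value + 1) scale, which understates the change of low genes. With 4 residual degrees of freedom, the spread of each gene is shared across genes by limma. The gene numbers of 14480 of the 14492 genes in the table were found in GENCODE M21, the source of the GRCm38 coordinates; whether the authors used that release is not given in the sources used here.

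Gene lists for liver functions, cell types, cholinergic signalling and responses to a virus numbered 32. The 31 with at least 5 measured genes were tested with camera at a preset correlation of 0.01 on the same values, adjusted over the lists; the list of pancreas and gut markers had 1 measured gene and was not tested. Some genes are in more than 1 list, up to 4 in a list. Counts of a list are out of its measured genes. These were 14 of 28 listed for monocytes, dendritic cells and neutrophils, 8 of 18 for B and plasma cells and 28 of 39 for T and NK cells. They were 30 of 57 for cytokines and 15 of 28 for female-biased genes. A gene can pass the filter through 1 group, as Pdcd1 did (mean 0.357 CPM in vehicle, 3.53 in Chrna4-labelled) and, the other way, Timd4 (10.1 and 0.476). Camera with a correlation estimated from the data, and fry, were alternatives. Further lists for hypotheses were written after the results of these lists were seen.

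The genes named in the text were chosen by rule. The rule takes Chrna4; the 8 largest rises and the 8 largest falls among genes past the threshold whose groups do not overlap and whose mean is at or above the median of tested genes (20.3), without predicted genes and immune receptor segments; the 3 members with the lowest p that moved in the direction of each called list; and the member with the lowest p of each other list that has one past the threshold. It gave 83 genes, and other genes are said to be named after their values were seen. Genes with near-identical copies, such as the Mup, Cyp2a, Cyp2c, Cyp3a, Gstm, Gsta, Oas1, Tgtp and H2 families, have uncertain values, since how shared reads were counted is not given.

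Libraries of a group were compared before averaging, by chi-square per degree of freedom over genes with at least 10 reads in a pair. It was 47.5 to 65.7 within vehicle and 10.3 to 17.7 within the Chrna4-labelled group, all far above 1. All 6 libraries were therefore counted as separate samples. By this measure the vehicle libraries differed more from each other, whereas the limma fit takes 1 spread per gene for both groups. The limma step was tested on simulated data drawn from the real means, library sizes and dispersions with 200 genes changed, over 12111 tested genes. It recovered 70 of 100 genes changed 2-fold and 97 of 97 changed 4-fold, with 13 false calls among 180. Camera called a simulated raised list and not a simulated unchanged list. The simulated genes were drawn independently, so this does not test the preset correlation on lists whose genes move together. The simulated changes went up and down in equal number, without the difference in scaling factors between the groups. They were also fewer than the 2962 genes called in the data. The simulation therefore does not test how the results depend on scaling. In the data the estimated correlation reached 0.80, for macrophage markers.

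The settings to vary, chosen then, were median centring, quantile normalization, no filter, a mean of at least 5, a pseudocount of 0.1, leaving out each library, a 2-fold minimum, an adjusted p of 0.1 and the authors' own p-values. Chosen after seeing the data were plain library totals, the replicate number as a block, and edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma-voom on the recovered reads of the same genes. The quasi-likelihood test called 2841 genes. Single values were compared with exact 2-sided permutation tests, whose smallest p with 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9.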

Results

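Liver RNA was sequenced from 6 male C57BL/6J mice, aged 8 weeks at the start and kept for 2 weeks on a high-fat diet that began with the injection. The labels put 3 libraries in a vehicle group and 3 in a group given an adenovirus, a virus used as a gene carrier, that overexpresses Chrna4, the alpha 4 subunit of the nicotinic acetylcholine receptor. The comparison asks what this injection did to gene expression in the liver. Each library is polyadenylated RNA read as 150 bp pairs, and the whole reads recovered from the deposited values numbered 15191600, 20224900 and 22440300 in the vehicle libraries and 14959300, 16840900 and 17023500 in the others. A second label says that mice were injected with adenovirus without naming a group, so whether the vehicle mice received a virus that lacks Chrna4 is not stated.

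Mouse Chrna4, the gene that the label says was overexpressed, was not higher in the libraries labelled with it. Chrna4 (ENSMUSG00000027577) is a protein-coding gene on the minus strand of chromosome 2, 181018380 to 181043546 in GRCm38. Its values in reads per 1000000 reads of the scaled library total (CPM) were 1.70, 4.99 and 3.38 in the vehicle libraries, from 22, 93 and 68 reads. In the libraries labelled Chrna4 adenovirus they were 3.70, 2.17 and 3.82, from 63, 41 and 72 reads. The log2 fold change of 0.0069 had a 95% interval from -0.68 to 0.69 (limma, adjusted p = 0.993), and the authors' deposited table gives -0.073 with an adjusted p of 0.954. The check of the labels by this gene thus did not bear them out at the depth of these libraries and the spread between them. It does not contradict them either, since whether the vector's transcript is counted as mouse Chrna4 is not given in the sources used here. Every direction below compares the libraries labelled Chrna4 adenovirus (called Chrna4-labelled) with those labelled vehicle.

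The Chrna4-labelled livers held more RNA of most listed matrix, cell cycle and antigen presentation genes and of interferon-stimulated genes such as Irf1. They held less of the major urinary proteins as a sum, of Cyp2c50, Cyp2c54 and Cyp2c37, 3 genes of cytochrome P450 enzymes, and of the bile acid uptake transporter genes Slco1b2, Slco1a1 and Slc10a1. Of 12099 genes tested, 2962 passed an adjusted p of 0.05 with limma, 1721 of them higher and 1241 lower. At least a 2-fold change was seen in 772 of the higher and 138 of the lower genes. The 3 Chrna4-labelled values lay apart from the 3 vehicle values in 2954 of the changed genes and in 43.0% of all tested genes, where chance gives 10%. The test favours genes whose groups lie apart, so the first count is not separate evidence. All genes share the same 6 libraries and are not independent, so the second is a description and not a test.

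The first principal component held 83.7% of the variance of the 1000 most variable genes and separated the groups. The 3 Chrna4-labelled libraries lay close together, with Spearman correlations of 0.989 to 0.994 across genes. Vehicle replicates 2 and 3 correlated at 0.990, and vehicle replicate 1 stood apart from both at 0.978 and 0.974. By limma, without vehicle replicate 1, 3331 genes changed, 2755 of them shared with the 2962. Without vehicle replicate 2 and 3 the count was 2403 and 2821. Each fit without 1 library had 5 libraries, so the number of libraries does not account for differences between these fits, whose cause was not tested. The count was lower, at 1866, 1442 and 1696, without replicate 1, 2 and 3 of the Chrna4-labelled group. In that order, the median log2 fold change of interferon-stimulated genes was 0.88, 0.82 and 0.93, against 0.88 with all libraries. That of respiratory chain genes was -0.49, -0.43 and -0.45, against -0.45. Cell cycle genes varied more, at 0.95, 1.27 and 1.22 against 1.17.

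**Figure D1:**
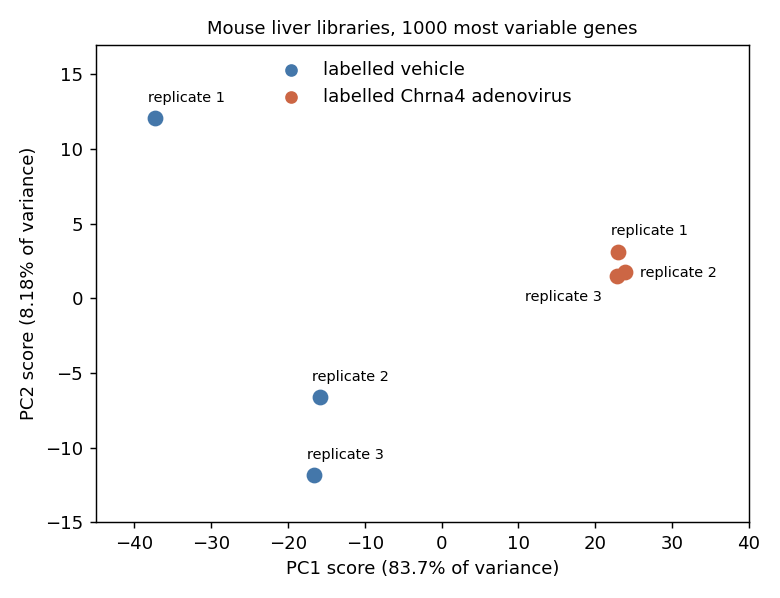
Scores of the 6 liver libraries on the first and second principal components (percent of variance on each axis) of log2(value + 1) over the 1000 most variable tested genes; each point is 1 library, coloured by its label. The Chrna4-labelled libraries lie between 22.8 and 23.9 on the first component, and vehicle replicate 1 at -37.3 lies apart from vehicle replicates 2 and 3 at -15.9 and -16.5.

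The scale of the libraries matters for the falls. The deposited values are scaled to library totals multiplied by a factor of 0.853 to 0.922 in vehicle and 1.11 to 1.14 in Chrna4-labelled libraries. With plain library totals the median log2 fold change of all genes moved up by 0.31, and 4852 genes changed, 93.0% of them higher against 58.1% with the authors' scaling. The fold changes below follow the authors' scaling, so that they are relative to the bulk of genes, and counts and some medians with plain totals stand beside those of the lists.

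Among abundant genes whose groups do not overlap, the largest rise was that of Gpnmb, a transmembrane glycoprotein of macrophages (chromosome 6, 49036546 to 49070929), from 1.22 ± 1.14 to 42.6 ± 3.93 CPM (mean ± SD, n = 3 per group), a log2 fold change of 4.41 with a standard error of 0.30 (limma, adjusted p = 0.000240). The fibrillar collagen gene Col1a1 (chromosome 11, 94936224 to 94953042) rose from 8.22 ± 3.63 to 86.4 ± 6.59, and its partners Col3a1 and Col1a2 rose by 2.99 and 2.52 on the log2 scale. Gstm3, a glutathione S-transferase (chromosome 3, 107963696 to 107969283), rose from 12.9 ± 0.578 to 129.9 ± 28.3 (log2 fold change 3.21). Lpl, which hydrolyses circulating triglycerides, rose by 2.93, and it was low in vehicle replicate 1, at 6.64 against 25.2 and 30.3 CPM in the others. The interferon-induced GTPase gene Tgtp1 and the class II antigen presentation gene H2-Eb1 rose by 2.75 and 2.44, and both were low in vehicle replicate 1, at 1.08 against 16.9 and 17.03 for Tgtp1 and 16.4 against 86.1 and 81.0 for H2-Eb1. Adjusted p-values of these 8 genes lay between 7.39e-05 and 0.0262 (limma). Tgtp1 lost its call without any 1 of the Chrna4-labelled replicates (limma, adjusted p from 0.0649 to 0.0925) and with DESeq2 (0.0648), and H2-Eb1 without replicate 2 of that group (0.0527).

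By the same rule, with a mean of at least 20.3 CPM, the 8 largest falls were those of genes of major urinary proteins, pheromone carriers that the male liver secretes: Mup12 (-4.75), Mup7 (-4.67), Mup1 (-4.08), Mup15 (-3.65), Mup17 (-3.62), Mup13 (-3.42), Mup16 (-3.32) and Mup18 (-3.11), with adjusted p-values between 0.000283 and 0.0321 (limma). Mup18 lost its call without vehicle replicate 3 and without each Chrna4-labelled replicate (adjusted p from 0.0561 to 0.109). These genes are near-identical copies in 1 cluster on chromosome 4, so the value of a single copy is uncertain. Summed over the 20 Mup genes in the table, the level fell from 52392 ± 14602 to 9595 ± 1942 CPM (mean ± SD, n = 3 per group; exact permutation test, 2-sided p = 0.1, the smallest this design allows). Their share of all recovered reads, which does not depend on the scaling, fell from 4.64% ± 1.18 to 1.08% ± 0.232 (SD, n = 3 per group; exact permutation test, 2-sided p = 0.1). Of the 20 tested singly, 15 passed as lower and 0 as higher.

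**Figure D2:**
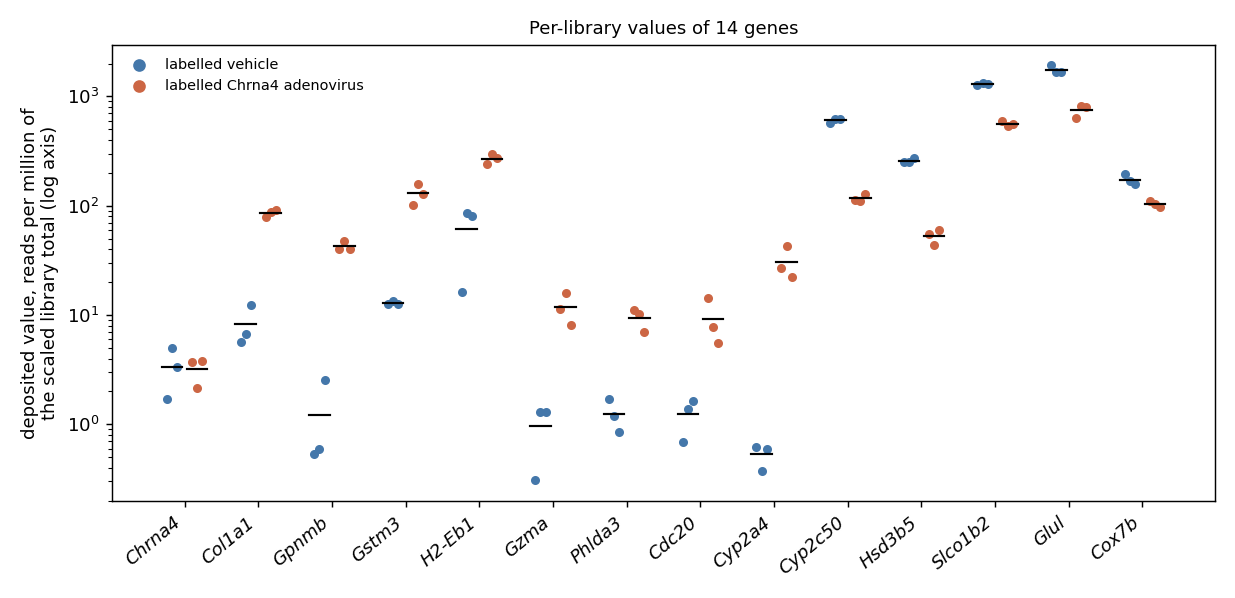
Deposited value of each library (CPM of the scaled library total, log axis) for 14 named genes; points are libraries, coloured by label, and lines are group means (n = 3). Chrna4 overlaps between the groups, and in the other 13 genes plotted the groups lie apart.

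Among the 31 lists tested, that of matrix genes had the median farthest from 0. Of 30 measured markers of stellate cells, the collagen-producing cells of the liver, and of the matrix, 26 rose and 0 fell (27 higher adjusted over the list alone), with a median log2 fold change of 1.53. Its members with the lowest p were Col1a2, Col1a1 and the type V collagen gene Col5a2, which rose by 2.52, 3.31 and 2.07, with adjusted p-values between 0.000178 and 0.000240 (limma). With plain totals 29 rose and the median was 1.81. Camera called the list raised (adjusted p = 4.79e-21), and the call was lost at adjusted p = 0.0840 with an estimated correlation.

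Immune genes rose in several lists. Of 48 interferon-stimulated genes, 26 rose and 0 fell (38 higher adjusted over the list alone), among them Irf1 (1.06), Oas1g (1.66) and Lgals3bp (0.97): Irf1 is a transcription factor and Oas1g an enzyme of the antiviral response. Antigen presentation genes rose in 22 of 26 (22 adjusted over the list alone), including the peptide transporter gene Tap1 (0.99), H2-Q4 (0.85) and Ciita (2.32), the regulator of class II genes. Of 30 cytokine and chemokine genes 15 rose (17 higher and 1 lower adjusted over the list alone), including Cxcl16 (1.47), Il1rn (2.06) and Ccl9 (1.02). With plain totals 44 interferon-stimulated, 24 antigen presentation and 18 cytokine genes rose and 0 fell (limma). The 9 genes named here had adjusted p-values between 0.000396 and 0.00368 (limma). Camera called the 3 lists raised, with adjusted p-values of 4.25e-12, 2.11e-09 and 5.04e-06 in that order; with an estimated correlation the adjusted p was 0.329, 0.269 and 0.0840, and no call held. Without Chrna4-labelled replicate 1, 2 and 3, the count of higher genes was 13, 10 and 15 for interferon-stimulated genes and 13, 10 and 13 for antigen presentation (limma).

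Markers of immune cells rose beside them. For T and NK cells 16 of 28 markers rose (20 adjusted over the list alone), with the cytotoxic granule gene Gzma rising from 0.962 ± 0.566 to 11.8 ± 3.86 CPM (mean ± SD, n = 3) and the inhibitory receptor genes Pdcd1 and Lag3 by 1.73 and 1.0 on the log2 scale. B and plasma cell markers rose in 4 of 8 (7 adjusted over the list alone): Jchain (2.70), Mzb1 (1.16) and Cd22 (1.17) and Cd37 (0.63), the last named after its value was seen. Monocyte, dendritic cell and neutrophil markers rose in 11 of 14 (12 adjusted over the list alone), including the monocyte chemokine receptor gene Ccr2 (1.75), Itgax (2.68) and Csf3r (1.34). Kupffer cell and macrophage markers rose in 18 of 25, among them Gpnmb, Trem2 (2.36) and Cd9 (1.42). Another 2 of them fell, Cd163 (-3.42, adjusted p = 0.000633 with limma) and Timd4 (-2.78, adjusted p = 0.00147), both markers of macrophages that reside in the liver and both named after their values were seen (19 higher and 2 lower adjusted over the list alone). With plain totals the higher markers numbered 22 for T and NK cells, 8 for B and plasma cells, 12 for monocytes, dendritic cells and neutrophils and 19 for macrophages, with 2 macrophage markers lower (limma). Adjusted p-values of the genes named by rule lay between 0.000240 and 0.00823 (limma). Camera gave adjusted p-values of 9.10e-08 for T and NK cells, 0.000310 for B and plasma cells, 3.19e-07 for monocytes, dendritic cells and neutrophils, and 1.65e-06 for macrophages. With an estimated correlation the adjusted p was 0.329, 0.252, 0.217 and 0.418, and none of the calls held. Without Chrna4-labelled replicate 1, 2 and 3, 8, 7 and 9 T and NK cell markers were higher (limma).

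Vehicle replicate 1 was low in these genes. Its median difference from the mean of vehicle replicates 2 and 3 was -0.85 on the log2 scale over interferon-stimulated genes, -0.44 over antigen presentation, -0.21 over cytokines, -0.69 over T and NK cells, -0.43 over B and plasma cells, -0.63 over monocytes, dendritic cells and neutrophils, and -1.13 over macrophages. It was -0.17 over matrix genes and -0.39 over cell cycle genes. Its largest differences in other lists were -0.97 over cholesterol synthesis and uptake and 0.74 over the 5 adipocyte markers. Without that library the count of higher genes was 31 for interferon-stimulated genes, 22 for antigen presentation, 16 for cytokines, 16 for T and NK cells, 4 for B and plasma cells, 11 for monocytes, dendritic cells and neutrophils, 28 for matrix and 36 for cell cycle genes. Macrophage markers then had 19 higher and 6 lower. The counts held, but the median log2 fold changes were smaller without that library. They went from 0.88 to 0.56 for interferon-stimulated genes, 0.70 to 0.53 for antigen presentation and 0.73 to 0.62 for cytokines. Those of T and NK cells went from 0.93 to 0.68, of macrophages from 1.16 to 0.87, of matrix from 1.53 to 1.47 and of cell cycle genes from 1.17 to 0.97.

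Genes of cell division rose, with 38 of 46 cell cycle genes higher and 1 lower, Tk1 (-0.45, named after its value was seen); adjusted over the list alone the counts were 39 and 2. The mitotic genes Ccnb1, Ccnb2 and Cdc20 rose by 1.85, 1.87 and 2.12; Cdc20 went from 1.24 ± 0.490 to 9.24 ± 4.64 CPM (mean ± SD, n = 3). Of 26 targets of the tumour suppressor p53 and DNA damage genes, 17 rose and 0 fell (18 higher and 2 lower adjusted over the list alone). Among them were the receptor gene Eda2r (2.26), Phlda3 (2.21) and the kinase gene Plk2 (1.11). Adjusted p-values of these 6 genes lay between 0.000564 and 0.00287 (limma). Camera called both lists raised (adjusted p = 1.77e-13 for cell cycle and 3.69e-07 for p53), and with an estimated correlation the adjusted p was 0.269 and 0.217, so neither call held. With plain totals 42 cell cycle and 20 p53 and DNA damage genes were higher, and 0 were lower (limma). Without Chrna4-labelled replicate 1, 11 p53 and DNA damage genes were higher, and without vehicle replicate 3, 2 were lower (limma). Markers of T and NK cells and of macrophages, with medians of 0.93 and 1.16, rose in the same libraries.

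Several lists of hepatocyte function fell, and the lowest median was that of genes expressed around the central vein. Of 17 pericentral genes 11 fell and 0 rose (12 lower and 1 higher adjusted over the list alone). They included Cyp2c37 (-1.99), Lect2 (-1.40) and Glul, the glutamine synthetase of the innermost hepatocytes, which fell from 1749 ± 152 to 749 ± 95.2 CPM (mean ± SD, n = 3). The list's median of -0.97 was -0.64 with plain totals, where 9 members were lower and 1 higher. Bile acid genes fell in 11 of 21 (13 adjusted over the list alone; 8 lower and 1 higher with plain totals), including the uptake transporter genes Slco1b2 (-1.20), Slco1a1 (-1.28) and Slc10a1 (-1.16); the list's median was -0.48, and -0.15 with plain totals. Slco1b2 lies on chromosome 6, 141629518 to 141686646. Xenobiotic metabolism genes went both ways, with 15 lower and 7 higher of 33 (17 and 8 adjusted over the list alone; 13 and 9 with plain totals). The cytochrome P450 genes Cyp2c50 (chromosome 19, 40089688 to 40113950), Cyp2c54 and Cyp2c37 fell by 2.36, 2.43 and 1.99 on the log2 scale, while the glutathione S-transferase gene Gstm3 rose. The list of xenobiotic metabolism had a median of -0.37, or -0.034 with plain totals. The genes named by rule in these 3 lists had adjusted p-values between 3.20e-05 and 0.000954 (limma). Camera called the 3 lists lowered at adjusted p = 9.10e-08, 6.22e-06 and 0.00434, and with an estimated correlation the adjusted p was 0.269, 0.0840 and 0.252, so no call held. Quantile normalization also ended the call of the xenobiotic list (adjusted p = 0.424, median -0.08), and without Chrna4-labelled replicate 2, 4 of its genes were higher (limma).

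Smaller falls ran through energy metabolism. Of 48 nuclear genes of the mitochondrial respiratory chain, 38 fell and 0 rose (44 lower adjusted over the list alone), with a median of -0.45; with plain totals the median was -0.12 and 7 fell. Cox7b, Ndufb8 and Ndufa5 had log2 fold changes of -0.74, -0.65 and -0.81. Fatty acid oxidation and PPARalpha target genes fell in 16 of 33 and rose in 1, the secreted hormone gene Fgf21 (1.14, named after its value was seen). Adjusted over the list alone 17 fell and 3 rose. The enoyl-CoA isomerase genes Eci2 and Eci1 and the carnitine palmitoyltransferase gene Cpt2 had log2 fold changes of -0.67, -0.69 and -0.50. With plain totals the median of the list went from -0.41 to -0.074, with 4 lower and 6 higher. Genes of gluconeogenesis, glycogen and insulin signalling fell in 7 of 24 (8 adjusted over the list alone), including Pygl (-0.51), Gpt (-0.54) and G6pc (-0.75); with plain totals 0 fell and 1 rose, and the median went from -0.40 to -0.061. With plain totals Cpt2, Pygl, Gpt and G6pc lost their calls (limma, adjusted p = 0.148, 0.145, 0.118 and 0.0737), and quantile normalization ended those of Pygl, Gpt and G6pc. G6pc also lost its call without Chrna4-labelled replicate 1 (adjusted p = 0.0526) and Gpt without replicate 2 (adjusted p = 0.0503). Adjusted p-values of these 9 genes lay between 0.00272 and 0.0156 (limma). Camera called the lists lowered at adjusted p = 3.87e-16, 7.03e-05 and 0.000125; with an estimated correlation the adjusted p was 0.252, 0.292 and 0.217, and no call held. Quantile normalization also ended the calls of the fatty acid oxidation list (adjusted p = 0.655, median -0.14) and the gluconeogenesis list (adjusted p = 0.710, median -0.071). Without Chrna4-labelled replicate 1, 2 and 3, the count of lower genes was 22, 16 and 18 for the respiratory chain, 9, 7 and 11 for fatty acid oxidation and 3, 2 and 4 for gluconeogenesis (limma). It was 11 for gluconeogenesis without vehicle replicate 1, and without each library in turn 0 to 3 genes of fatty acid oxidation were higher.

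General hepatocyte markers fell in 7 of 19 (7 adjusted over the list alone), among them the secreted protein genes Rbp4 (-0.90), Apoa2 (-1.20) and Ttr (-0.84). Their median of -0.39 went to -0.057 with plain totals, where 4 fell, and to 0.14 with quantile normalization, a change of sign that ended the call (camera, adjusted p = 0.648). Of 19 circadian clock genes 4 fell, Usp2 (-0.54), Tef (-0.52) and Nfil3 (-0.66) and, named after its value was seen, Per3 (-0.73); the core clock gene Arntl rose by 0.56, also named after its value was seen (8 lower and 1 higher adjusted over the list alone). The clock list's median of -0.32 went to 0.011 with plain totals, and 0 of its genes then fell and 2 rose. Usp2, Tef and Nfil3 lost their calls with plain totals (limma, adjusted p = 0.168, 0.217 and 0.122). Nfil3 lost its call also without vehicle replicate 3 and without each Chrna4-labelled replicate (from 0.0681 to 0.106), and Tef without Chrna4-labelled replicate 1 or 2 (from 0.0850 to 0.0857). Without Chrna4-labelled replicate 1, 2 and 3, 4, 4 and 6 hepatocyte markers and 1, 1 and 2 clock genes were lower (limma). Arntl did not pass without vehicle replicate 3 or any Chrna4-labelled replicate. Quantile normalization ended the calls of Rbp4, Ttr and Tef. The 6 genes named by rule had adjusted p-values between 0.00297 and 0.0294 (limma). Camera gave adjusted p = 1.49e-05 for hepatocyte markers and 0.00590 for clock genes; with an estimated correlation the adjusted p was 0.178 and 0.269, and neither call held.

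Of genes that differ between male and female livers, many male-biased ones fell in these male mice and some female-biased ones rose. Male-biased genes fell in 16 of 24 (17 adjusted over the list alone) and rose in 1, Gstp2 (0.75, named after its value was seen), and 0 male-biased genes were higher when any 1 library other than vehicle replicate 1 was left out (limma). The median was -0.88, or -0.55 with plain totals, where 12 fell and 1 rose. The steroid dehydrogenase gene Hsd3b5 (chromosome 3, 98618634 to 98630252) fell from 258 ± 11.5 to 52.9 ± 8.27 CPM (mean ± SD, n = 3), and Nat8 and the deiodinase gene Dio1 had log2 fold changes of -2.21 and -1.20. Female-biased genes rose in 4 of 15 (7 adjusted over the list alone): the steroid hydroxylase gene Cyp2a4, from 0.529 ± 0.134 to 30.8 ± 10.8, Atp6v0d2 (1.68), Cyp3a16 (1.5) and, named after its value was seen, Rtn4 (0.65). With plain totals 10 rose and 1 fell, and the median went from 0.51 to 0.84 (limma). Sult1d1 fell (-0.78, also named after its value was seen; 2 lower adjusted over the list alone). Without Chrna4-labelled replicate 1, 2 female-biased genes were higher, and without vehicle replicate 3, 3 were lower (limma). Cyp3a16 lost its call with quantile normalization (limma, adjusted p = 0.0528) and without Chrna4-labelled replicate 1 or 3 (limma, adjusted p from 0.0776 to 0.0789). The female-biased list was not called without vehicle replicate 3 or without Chrna4-labelled replicate 1 (camera, adjusted p = 0.122 and 0.0532), nor with plain totals (0.416), no filter on low values (0.0627, median 0.22) or a mean of at least 5 (0.158). Atp6v0d2, a proton pump subunit, is also made by macrophages, whose markers rose. The 6 genes named by rule had adjusted p-values between 0.000111 and 0.0195 (limma). Camera called the male-biased list lowered (adjusted p = 3.17e-11) and the female-biased list raised (adjusted p = 0.0263), and with an estimated correlation the adjusted p was 0.130 and 0.269, so neither call held.

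Another 11 of the 31 lists were not called by camera. Endothelial cell markers had a median of -0.069 (0.25 with plain totals), with 1 of 24 higher, Lyve1 (1.38), and 3 lower, Clec4g (-0.41), Wnt2 (-0.88) and Vwf (-0.87). Lipid droplets and lipid uptake had 6 of 19 genes higher, the fatty acid binding protein gene Fabp4 (0.84), Lpl (2.93), Cidec (1.99), Cd36 (1.18), Hilpda (0.83) and Plin3 (0.49), and 3 lower, Fabp1 (-0.88), Cideb (-0.44) and Fitm1 (-1.22). Fatty acid and triglyceride synthesis had 5 of 22 lower, Thrsp (-1.37), Dgat2 (-0.67), Pklr (-1.42), Agpat2 (-0.55) and Acss2 (-0.68), and 1 higher, Scd2 (1.21). Cholesterol synthesis and uptake had 3 of 25 lower, Tm7sf2 (-0.75), Stard4 (-0.68) and Ebp (-0.56); without vehicle replicate 1 there were 10, and camera then called the list lowered (adjusted p = 3.74e-06). With plain totals these counts changed, to 7 higher and 1 lower for endothelial markers, 7 and 1 for lipid droplets and uptake, 4 and 3 for fatty acid and triglyceride synthesis and 1 and 0 for cholesterol (limma). The last 2 medians then went from -0.20 to 0.14 and from -0.15 to 0.18, while camera, which sets a list against other genes, called both lowered (adjusted p = 0.00194 and 0.00153). Fatty acid and triglyceride synthesis was also called lowered without vehicle replicate 1 or 3 or Chrna4-labelled replicate 3 (camera, adjusted p from 0.00202 to 0.0257), and cholesterol without the last of these (0.00346). Clec4g lost its call with plain totals and without Chrna4-labelled replicate 2 (limma, adjusted p = 0.549 and adjusted p = 0.0626), and Tm7sf2 with plain totals (0.0509). Without each library in turn, the counts ranged from 0 to 3 higher and 0 to 6 lower for endothelial markers, 4 to 6 and 0 to 4 for lipid droplets and uptake, 1 to 3 and 4 to 7 for fatty acid and triglyceride synthesis, and 0 to 1 and 1 to 10 for cholesterol (limma). The highest endothelial count of lower genes was that without vehicle replicate 1, where the median was -0.18. That of lipid droplets and uptake was then 0.19. The median of cholesterol genes was -0.52 without vehicle replicate 1 and 0.049 without vehicle replicate 2, and that of fatty acid and triglyceride synthesis went from -0.37 without vehicle replicate 3 to -0.046 without vehicle replicate 2. Genes of these 4 lists other than Clec4g, Fabp4, Lpl, Thrsp and Tm7sf2 were named after their values were seen.

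The acute phase list had 5 of 32 higher, Lcn2 (1.90), Cd14 (1.12), Steap4 (0.67), Hpx (0.54) and Saa2 (1.02), and 3 lower, Serpina3m (-0.73), Crp (-0.62) and Saa4 (-0.98). The unfolded protein and integrated stress response list had 5 of 30 higher, Atf3 (2.32), Asns (1.84), Trib3 (0.89), Psat1 (1.30) and Phgdh (0.86), and 3 lower, Herpud1 (-0.84), Sel1l (-0.43) and Creb3l3 (-0.47). Periportal genes had 4 of 17 higher, Aldh1b1 (1.45), Ctsc (0.81), Hsd17b13 (0.36) and Cdh1 (0.92), and 2 lower, Pigr (-0.62) and Igf1 (-0.50). Bile duct markers had 2 of 7 higher, Sox9 (0.90) and Ddit4l (0.93), erythroid markers 1 of 7 lower, Alas2 (-0.77), and adipocyte markers 1 of 5 higher, Fabp4. Cholinergic genes had 1 of 5 higher, the nicotinic receptor modulator gene Lynx1 (0.72, adjusted p = 0.0331 with limma), a call lost with quantile normalization (adjusted p = 0.245) and without vehicle replicate 2 or Chrna4-labelled replicate 1 or 2 (from 0.0929 to 0.114). Sox9 lost its call with quantile normalization (limma, adjusted p = 0.0539) and without vehicle replicate 2 or Chrna4-labelled replicate 1 or 3 (adjusted p from 0.0686 to 0.0883). Lcn2, Atf3, Aldh1b1, Sox9, Alas2, Fabp4 and Lynx1 were named by rule (adjusted p-values between 0.000255 and 0.0331, limma), and the other genes of these lists after their values were seen. With plain totals, 15 acute phase genes were higher and 1 lower, and the list's median of 0.077 was 0.41, or 0.45 with quantile normalization. The stress response then had 8 higher and 1 lower, periportal genes 6 and 0 and erythroid markers 0 and 1, with 3 bile duct, 2 adipocyte and 2 cholinergic genes higher (limma). Camera called the acute phase and periportal lists raised with quantile normalization (adjusted p = 1.81e-05 and 0.000369, periportal median 0.25), and erythroid markers lowered without vehicle replicate 2 or Chrna4-labelled replicate 3 (adjusted p from 0.0263 to 0.0349). Without vehicle replicate 1, 9 acute phase genes were higher and 4 lower, and 5 stress response genes were lower (limma). Without each library in turn, the counts ranged from 2 to 9 higher and 2 to 4 lower for the acute phase, 4 to 5 and 2 to 5 for the stress response and 2 to 4 and 1 to 3 for periportal genes. For bile duct, adipocyte and cholinergic genes they ranged from 0 to 2, 1 to 2 and 0 to 2 higher. Of the uncalled lists, 6 had a median whose sign depended on the library left out: the lipid droplet and cholesterol lists, endothelial markers (-0.18 to 0.06), the acute phase (-0.053 to 0.19), adipocyte markers (-0.16 to 0.48) and cholinergic genes (-0.14 to 0.089). Camera gave the 11 lists adjusted p-values from 0.0766 for fatty acid and triglyceride synthesis to 0.837 for cholinergic genes. The median and the mean log2 fold change differed in sign for cholinergic genes (-0.05 and 0.24), lipid droplets and uptake (-0.06 and 0.25), stress response (-0.094 and 0.092) and periportal genes (-0.15 and 0.045), with camera upward for the first 2 and downward for the others. Adjusted over the list alone, the counts of the 11 uncalled lists lay between 0 and 6 higher and between 0 and 6 lower.

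**Figure D3:**
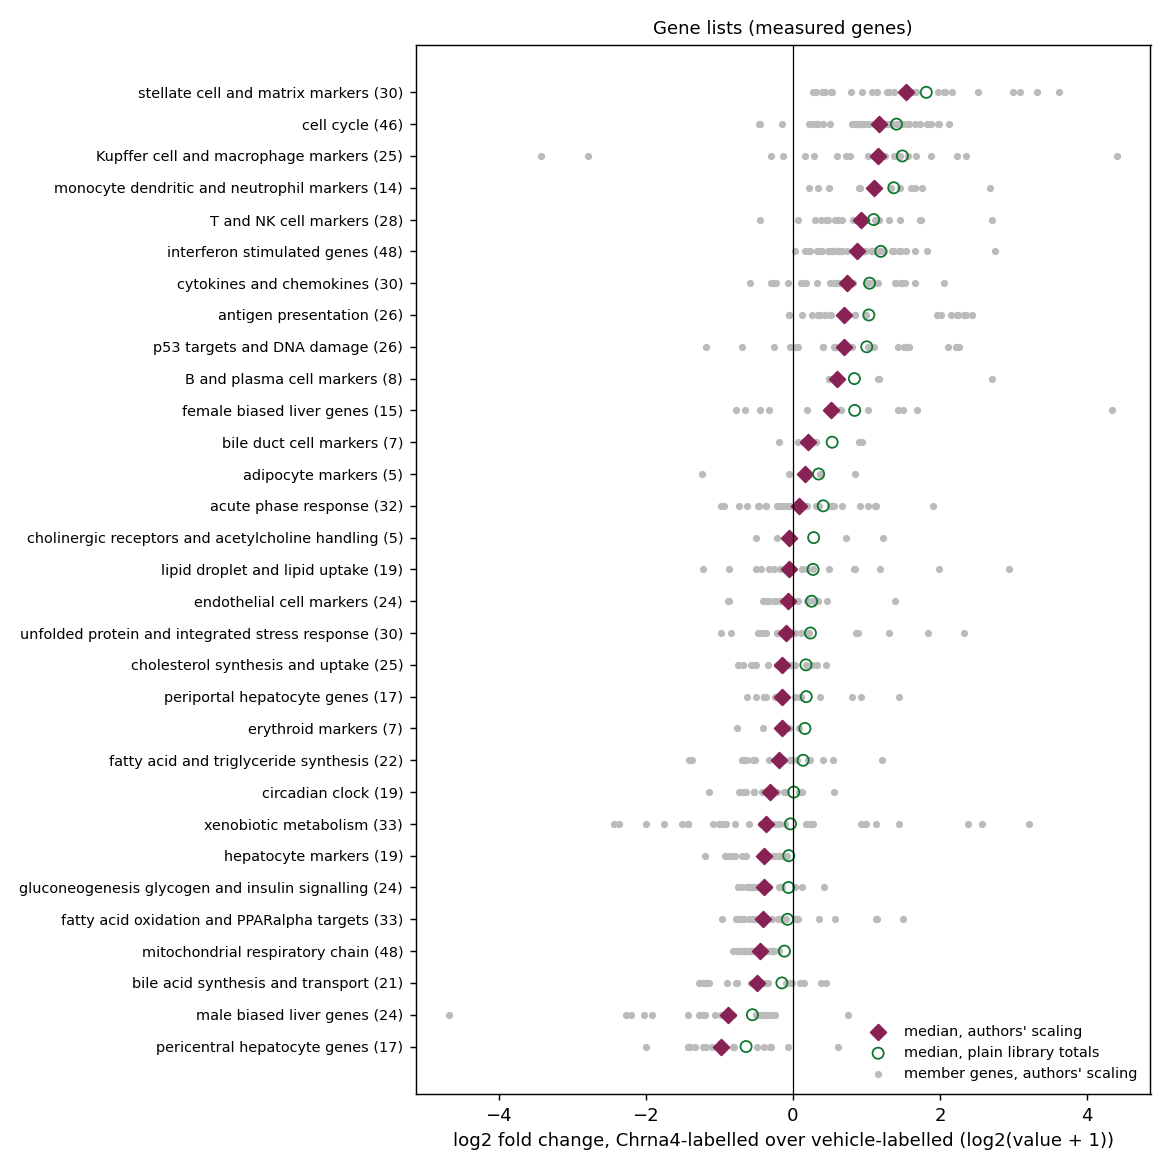
Log2 fold change of Chrna4-labelled over vehicle libraries (log2(value + 1), x axis) for the 31 gene lists tested, with the number of measured genes in brackets; grey points are member genes and diamonds their median with the authors' scaling, and open circles are the median with plain library totals. The matrix list has the highest median (1.53) and the pericentral list the lowest (-0.97); with plain totals every median is higher, and that of the clock list changes sign, as do those of 8 lists that camera did not call.

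Camera called 11 lists raised and 9 lowered with its preset correlation of 0.01, and 0 with an estimated correlation, where 2 raised and 4 lowered lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.0840 (matrix, bile acid and cytokine lists). The other splits of the 6 libraries into 3 and 3 gave 3 to 20 called lists by the same preset test. By fry, which asks whether a list moves on balance and not whether it moves more than other genes, 12 lists were raised and 9 lowered, with bile duct markers (adjusted p = 0.0359) added to those that camera called.

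The authors' deposited workbook has 2 sheets of genes that they selected. Of 36 tested genes on the cytokine sheet, 31 rose and 2 fell, Col27a1 (-2.02) and Col5a3 (-0.62). In the main column of the second sheet 47 of 65 tested genes rose and 2 fell, Col27a1 and Il1rap (-0.71). A later column of that sheet has 4 other genes, counted apart; 2 of them were tested, Cxcr4 (1.07) and Cxcr6 (0.93), and both rose (limma). These genes were named after their values were seen, and a sheet selected on these libraries is not independent evidence of its direction. Across the whole table, the authors' deposited table has 3491 genes with an adjusted p under 0.05, 2171 higher and 1320 lower. Of the 2962 genes called here, 2764 are among them, and all of those have the same direction in both.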

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

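Plain library totals, the block by number and the counting of recovered reads were chosen after seeing the data; the other settings were chosen before the data were examined. Of the 82 named genes other than Chrna4, 65 kept their direction and their side of the threshold under all alternatives other than the block that gave them a value, and no named gene past the threshold changed direction. With the authors' own p-values, median centring, no filter, a pseudocount of 0.1, an adjusted p of 0.1, edgeR, DESeq2 and limma-voom, counts of changed, higher and lower genes stayed within 1.5 times the main ones. With a 2-fold minimum 910 genes changed, 772 higher and 138 lower, by construction. With plain totals 4852 changed, 4511 higher and 341 lower, since every fold change moves up with the scaling; 9 named genes lost their call. With a mean of at least 5, 1036 genes were higher and the cytokine sheet had 20 higher, since fewer genes were tested. Quantile normalization left 5 lists lowered and 13 raised, the acute phase and periportal lists being added, ended the calls of the fatty acid oxidation, gluconeogenesis and xenobiotic lists, turned the hepatocyte marker median to 0.14 and ended 9 calls of named genes; the cause was not tested. With an estimated correlation camera called 0 lists raised and 0 lowered (2 and 4 at an unadjusted p under 0.05), and fry called 12 and 9. The female-biased list lost its call with no filter, a mean of at least 5, plain totals and without vehicle replicate 3 or Chrna4-labelled replicate 1. Lowered calls were gained by fatty acid and triglyceride synthesis (plain totals, without vehicle replicate 1 or 3 or Chrna4-labelled replicate 3), cholesterol (plain totals, without vehicle replicate 1 or Chrna4-labelled replicate 3) and erythroid markers (without vehicle replicate 2 or Chrna4-labelled replicate 3). With a mean of at least 5, 5 lists kept too few genes for a value: T and NK cells, B and plasma cells, cholinergic genes, bile duct and adipocyte markers.

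The Chrna4 log2 fold change, near 0 with either sign, was -0.044 with median centring, -0.35 with quantile normalization, -0.064 with edgeR, -0.071 with DESeq2 and -0.037 with limma-voom, and lay between -0.30 and 0.27 without each library in turn; it passed the threshold under none of these, and the cause of the sign was not tested. Its precision is limited by the spread between libraries, 3.35 ± 1.65 CPM in vehicle and 3.23 ± 0.917 in Chrna4-labelled ones (mean ± SD, n = 3). Part of that spread can come from its 22 to 93 reads per library. Without each library in turn the count of changed genes lay between 1442 and 3331. That of higher genes lay between 946 and 1913 and that of lower genes between 496 and 1418. The lowest of each was without Chrna4-labelled replicate 2. All of these fits had 5 libraries, so the number of libraries does not account for the differences, whose cause was not tested. The column names share the numbers 1 to 3, and the labels pair no libraries. Same-numbered libraries did not deviate together (Pearson r across genes of -0.065 to 0.021, and -0.067 to 0.075 for other numbers). With the replicate block limma called 2418 genes, 1494 higher and 924 lower, and 3 named genes did not pass, with 2 residual degrees of freedom. DESeq2 and limma-voom had been meant for a count table and were run on recovered reads instead.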

Other observations

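The tests of splits, of endothelial markers in vehicle replicate 1, of NRF2 targets and of growth hormone genes were fixed before their results were seen, and the other tests here were chosen after. Genes of this section that the rule did not name, such as Gsta1 and Ugt1a9, were named after their values were seen. Toll-like receptor genes, which sense microbial molecules, rose in 9 of 11 tested (limma), with a median log2 fold change of 1.38 and a range over the other scalings of 1.04 to 1.61. The largest rise was that of Tlr1, from 1.43 ± 0.858 to 8.89 ± 1.09 CPM (mean ± SD, n = 3 per group), and Tlr5 and Tlr12 did not pass. Genes named as chemokine receptors rose in 6 of 7 tested and chemokines in 9 of 16, with 0 lower in either (limma). Collagens went both ways, with 13 of 22 higher and 3 lower, Col27a1 (-2.02), Col5a3 (-0.62) and Col13a1 (-0.69). The medians of the 3 families were 1.07, 1.07 and 1.01, and stayed above 0 under each scaling. Members of these families are on the authors' sheets, so these counts are not independent evidence, and the families were taken up after their values were seen. Markers of macrophages and of monocytes, dendritic cells and neutrophils, with medians of 1.16 and 1.10, rose in the same libraries. Vehicle replicate 1 was low in both, and the families were not counted without it.

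Gstm3, Gsta1 and Ugt1a9 rose by 3.21, 2.57 and 2.38 on the log2 scale (limma), and a hypothesis is that targets of NRF2, a regulator of glutathione and redox genes, rose as a set. Of 27 measured targets that leave those genes out, 12 rose and 1 fell, Ces1g (-0.44), so that 44.4% rose, between the bounds of 50% and 25% set for and against it. The rises included Srxn1 (1.22), Hmox1 (1.04), Gsta2 (1.45) and Nqo1 (0.99), while Gclm (-0.15) and Txnrd1 (0.22) did not pass. The median was 0.36 and stayed above 0 under each scaling; camera gave an adjusted p of 0.000215 over 4 such lists, and 0.181 with an estimated correlation. The question stays open. The bounds were set for targets not seen before, but 6 of the listed genes are also in the lists of the report. The share among the unseen ones alone was not computed.

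Male-biased liver genes depend on growth hormone in textbook accounts, and a hypothesis is that its signalling genes fell too. Of 6 such genes 3 fell, Ghr (-0.96), Igfals (-1.03) and Igf1 (-0.50), or 50%, where over 50% had been asked for. The median of the list was -0.67, or -0.35 with plain totals. The feedback gene Socs2 had a log2 fold change of 0.36 and Cish of -0.83, neither past the threshold (limma, adjusted p = 0.509 and 0.373). Camera gave an adjusted p of 0.0370, and 0.242 with an estimated correlation. The test leaves the question open, and 1 of the genes, Igf1, is also in a list of the report.

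Cd163 and Timd4 fell while Gpnmb and Trem2 rose, and a hypothesis is that genes of resident Kupffer cells fell while those of lipid-associated macrophages rose. Of 10 lipid-associated genes that leave those out, 8 rose, among them Cd63 (2.14), Lgals3 (2.23), Ms4a7 (2.23) and Cx3cr1 (1.56), with an adjusted camera p of 1.87e-07 (0.0776 with an estimated correlation). Of the resident and lipid-associated genes, 6 and 5 are also in the lists of the report, so some of their values had been seen. Of 7 resident genes 1 fell, Fcna (-0.86), and 1 rose, Cd5l (1.45). Without vehicle replicate 1, which was low in macrophage genes, 5 fell and 2 rose. The medians of the lists differed by 1.33 on the log2 scale (exact permutation over genes, 2-sided p = 0.00848; genes are not independent), so lipid-associated genes may have risen against resident ones, but whether resident genes fell depends on 1 library.

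Immune and matrix genes rose while hepatocyte markers fell. A lower share of hepatocyte RNA alone would raise the markers of other cells alike. Matrix markers, however, lay 1.60 above endothelial markers in median log2 fold change (95% interval 1.25 to 1.93, resampling genes). For these lists this argues against a lower share as the sole cause. The intervals of this paragraph treat genes as independent, which they are not, so they do not measure the spread between mice. A scaling factor moves all genes of a library alike, except that low genes move less on the log2(value + 1) scale. With plain totals the T and NK cell median went from 0.93 to 1.10 and the endothelial one from -0.069 to 0.25. Scaling is argued against as the sole cause of the rises, since T and NK cell markers lay 1.0 above endothelial markers (95% interval 0.77 to 1.2). With quantile normalization, which is not a scaling by 1 factor, they lay 0.59 above (95% interval 0.36 to 0.84). Hepatocyte markers lay at -0.32 relative to endothelial markers (95% interval -0.64 to -0.11) but at 0.19 with quantile normalization (95% interval -0.18 to 0.44). With plain totals their median of -0.057 also lay below the endothelial one of 0.25. Their own fall went from -0.39 to -0.057 with plain totals, so for it an effect of scaling or of normalization stays open. An effect of the adenovirus itself cannot be told apart from an effect of Chrna4, since 0 libraries are labelled as given a virus without Chrna4, and both stay open.

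The real split of the libraries called 2962 genes, and 1 split of 10, the real one, gave as many by limma, with 0 in the highest of the others (525 at an unadjusted p under 0.05, against 4439 in the real one); for gene lists it called 20 and the highest other split 20, so that 2 splits gave as many. These splits are too few for a share under 0.05.

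Mouse Chrna4 was not higher in the Chrna4-labelled libraries. A single library with a wrong label is argued against, as the lowest correlation among the Chrna4-labelled libraries lay 0.0190 above the highest one between the groups. A candidate explanation is that the vector's transcript was not counted as mouse Chrna4, or was no longer made at 2 weeks. The upper 95% limit of the log2 fold change was 0.69, and no value here states the level that the vector should give, so these cannot be told apart.

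Vehicle replicate 1 was low in immune genes. Depth is argued against: after the reads of vehicle replicates 2 and 3 were thinned to its total, T and NK cell markers still lay at -0.71 on the log2 scale relative to them. Its endothelial markers differed from those of the other 2 vehicle libraries by -0.22, 0.47 above the difference in T and NK cell markers (95% interval 0.17 to 0.68, resampling genes). Fewer of all cells other than hepatocytes would lower both alike, so for these genes the values go against it as the sole cause. The interval treats genes as independent and compares 1 library with 2, so it does not measure the spread between mice. Neither test bears on its cholesterol genes, which lay at -0.97 relative to the other vehicle libraries, or on its 5 adipocyte markers, at 0.74. A difference between mice, in immune cells, interferon or metabolism, stays open. Apart from this share of cells, no biological explanation was tested, as the labels give none within a group.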
